A study of Rattus norvegicus with 12 samples.

How the data were processed

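Cartilage was dissected from the distal femoral condyles of female Sprague Dawley rats of 12 to 14 weeks, with 5 animals per group, and the arrays of a group came from 3 different rats. The groups were controls without exercise and rats exercised on a treadmill each day (45 min at 12 m/min) over 2, 5 or 15 days. Per the labels 300 ng of RNA were used for each array, a Rat Gene 1.0 ST array. The deposited values are on a log scale, read here as log2, and the submitters' processing notes name GCRMA and Partek version 17, with no settings, order or filters. In the deposited table the mean of the 3 controls of each probe set is 0 (largest size 3.33e-06), so values are relative to the controls and no absolute level is kept. The log base is not stated. GCRMA gives log2, and base 10 was excluded because the range within a probe set reached 6.54, where a 16-bit scanner spans 4.82, but a natural log was not excluded by the values, and the folds given depend on the base. Arrays have no read depth: the number of arrays limits the precision, and signal over background was not analysed here because no level is kept. The array medians lay between -0.01 and 0.03.

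The table holds 20717 probe sets on 12 arrays. Of these, 15013 named 1 gene, 323 named several and 5381 none, and only the first were used. They gave 14278 genes, of which 465 had several probe sets, whose values were averaged. The plan had been to use the brightest probe set of a gene and to try a filter on dim genes, but neither can be chosen from centred values, so the mean stands in its place. Gene identifiers matched the reference table for 14983 probe sets, and 0 symbols changed. Genomic positions were not analysed here, since no genome came with the series.

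Groups were compared with limma 3.58.1 in R 4.3.3, with 1 mean per group in 1 fit of all 12 arrays (8 residual and 4.51 prior degrees of freedom), no covariate, and Benjamini-Hochberg adjustment within each of the 6 comparisons at 0.05. A moderated F-test covered the 4 groups. A fold of 2 was used only to describe the calls. Replicates are separate rats, so no pairing was assumed. The 35 gene lists (24 of processes, 11 of cell types that the dissection could carry) held 906 genes, of which 796 were measured, 3 under a synonym. They were tested with camera at a preset correlation of 0.01, with at least 5 measured members, and also with an estimated correlation and with fry, which tests whether a list's genes move one way on balance. Of the panel of 20 cartilage genes 18 were measured. The groups, comparisons, tests, gene lists, panel, rule for named genes and other settings to try were fixed before the data were examined. That rule took, against controls, the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap. Between durations it took 5 of each, or the 5 with the smallest unadjusted p where fewer than 5 passed. It also took the 4 members with the smallest p of each called list, and the panel. Correlations of log2 fold changes between exercised groups were set beside 100 draws of simulated groups with no effect that shared the 3 controls.

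Simulated data took the spread of each gene from these values and drew its noise independently of other genes. In them a change added to genes in the 2-day comparison was recovered in 40.8%, 94.8%, 99.2% and 99.6% of genes for log2 changes of 0.5, 1, 2 and 3, with 4.24% of the calls false. A shift of 0.5 added to the glycolysis list had a camera adjusted p = 1.13e-04 with an estimated correlation. Since the simulated genes were not correlated, these values do not show how the tests perform on correlated genes. The other settings were a trended robust prior, array weights, quantile normalization once more, array medians subtracted, the replicate number as a block, probe sets not averaged, only the groups compared in the fit, an unadjusted p under 0.05 with a fold of 2, leaving out each array in turn, and the 2 other list tests. Settings added after seeing the data were the probe set with the lowest identifier, every deposited probe set, and leaving out 2 pairs of arrays rich in markers of other cell types.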

Results

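The series measured gene expression in articular cartilage taken from the condyles at the lower end of the femur of female Sprague Dawley rats. One group was not exercised (controls), and 3 groups went on a treadmill at 12 m/min for 45 min a day, for 2, 5 or 15 days. RNA of 3 rats per group was hybridised, 1 rat per array, to an Affymetrix rat array that covers whole transcripts, which gave 12 arrays. The design asks which genes of cartilage differ after exercise, and how the difference depends on the number of days. The deposited values are taken as log2, although their base is not stated, and each probe set's mean over the 3 controls was already subtracted from them, so differences between groups are kept and the level of a gene is not. Arrays have no read depth, and their number limits the precision: the median SD of a gene among the 3 rats of a group was 0.142 in controls and 0.124, 0.118 and 0.149 after 2, 5 and 15 days. Below, each ± is the standard error of a log2 difference from the limma fit with 3 rats per group, adjusted p is limma's Benjamini-Hochberg value, and gene list p-values are adjusted over 35 lists. Largest changes are named among the genes that passed and whose 3 arrays per group did not overlap between the groups compared.

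All exercised groups differed from the controls at many of the 14278 genes, and they differed far less among themselves. The first principal component, with 48.9% of the variance, placed the 3 controls between -47.7 and -33.0 and the 9 exercised arrays between -0.69 and 23.8. The second, with 15.5%, set the 15-day arrays apart. In all 3 exercised groups 919 genes were higher than in controls and 821 were lower at an adjusted p under 0.05. Among the genes higher in every group were the kinase gene Stk32b, the receptor tyrosine kinase gene Ret and the steroid receptor co-chaperone gene Fkbp5. Among those lower in every group were the neutrophil enzyme gene Mpo, the gelatinase gene Mmp9 and the cartilage matrix protein gene Matn3.

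**Figure D1:**
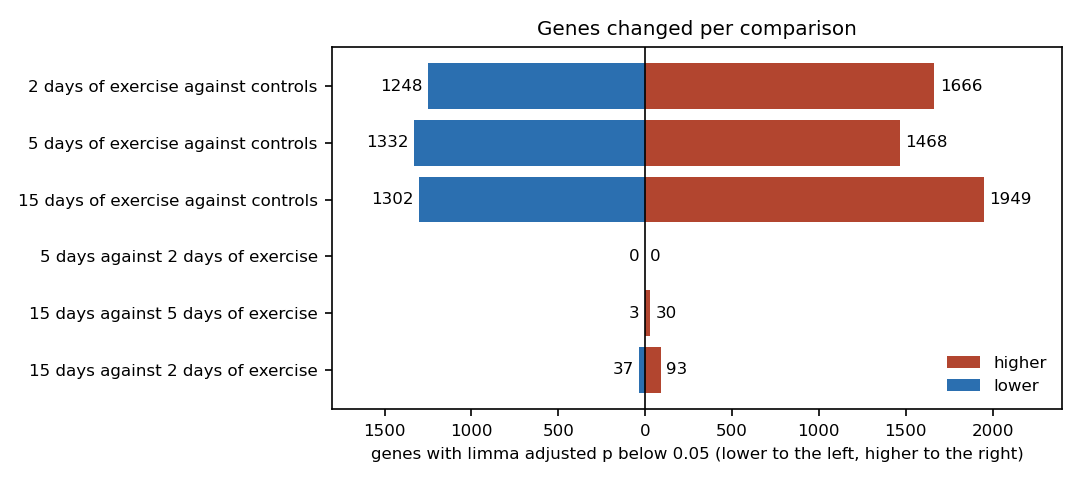
Number of genes with a limma adjusted p under 0.05 per comparison (horizontal axis, genes; lower to the left, higher to the right). The comparisons with controls call 2914, 2800 and 3251 genes, and the comparisons between durations call 0, 33 and 130.

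After 2 days of exercise camera called 9 lists higher and 13 lower than in controls, and no list with an estimated correlation between members (lowest adjusted p = 0.336). The lower lists included the cell cycle (24 of 26 genes passing) and granulocytes (14 of 17), and the higher ones heat shock (13 of 26), hypoxia (10 of 21), the glucocorticoid response and the clock (6 of 14 each). The largest rise was in Stk32b (3.24 ± 0.25, 9.48-fold, adjusted p = 5.46e-05). Next came the receptor tyrosine kinase Ret at 2.88 ± 0.33, and Fkbp5 at 2.65 ± 0.36. The transcription factor Zbtb16 rose by 2.60 ± 0.28, the microtubule-associated Eml5 by 2.55 ± 0.27, the serotonin receptor Htr1b by 2.38 ± 0.72 and the phospholipase Plce1 by 2.34 ± 0.22. The protease inhibitor Serpina1 (2.21 ± 0.40), the ATP-gated channel P2rx5 (2.19 ± 0.40) and the secreted chondrocyte protein Cytl1 (2.17 ± 0.22) completed the 10 largest rises, with adjusted p between 5.46e-05 and 0.0343. The erythroid carbonic anhydrase Car1 showed the largest fall (-3.26 ± 0.44, 9.60-fold lower, adjusted p = 5.39e-04). It was followed by Mmp9 (-3.17 ± 0.69), the defensin Defa5 (-3.17 ± 0.68), Fam111a (-3.13 ± 0.82), the neutrophil granule protein Ngp (-3.07 ± 0.95) and the linker histone H1f1 (-3.05 ± 0.33). S100a9 (-2.98 ± 0.73), Mpo (-2.76 ± 0.48), Matn3 (-2.76 ± 0.29) and the haemoglobin-stabilising Ahsp (-2.72 ± 0.51) were also among the 10 largest falls.

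In the cell cycle list, 24 of 26 measured genes fell at 2 days (24 adjusted over the list alone), with a median of -1.34 (camera adjusted p = 5.88e-22). With an estimated correlation between members its adjusted p = 0.336, and no list passed in any comparison with that setting. Cyclin B2 (Ccnb2) changed by -1.98 ± 0.18, the spindle checkpoint kinase Ttk by -1.23 ± 0.11, Aurkb by -1.72 ± 0.16 and the mitotic kinesin Kif20a by -1.46 ± 0.15. Of the granulocyte markers 14 of 17 fell (16 adjusted over the list alone, median -1.43), with Elane at -2.36 ± 0.25, Prtn3 at -1.26 ± 0.17, Fcnb at -2.21 ± 0.33 and Ctsg at -1.43 ± 0.23. Erythroid markers fell for 8 of 11 (9 adjusted over the list alone), including Epb42 (-1.47 ± 0.21), Hemgn (-1.90 ± 0.33) and Rhag (-1.78 ± 0.31). Lymphoid markers fell for 8 of 15 (8 adjusted over the list alone), including the recombinase Rag1 (-1.46 ± 0.19), Dntt (-1.45 ± 0.22), Cd79b (-1.503 ± 0.25) and Lck (-0.47 ± 0.09). The granulocyte, erythroid and lymphoid lists had camera adjusted p = 1.15e-09, 4.37e-06 and 4.37e-06, and each had adjusted p = 0.336 with an estimated correlation. Osteoblast and osteocyte markers fell for 7 of 13 (9 adjusted over the list alone), with Ifitm5 at -1.43 ± 0.15, Smpd3 at -1.35 ± 0.25, Col1a2 at -1.24 ± 0.24 and Col1a1 at -1.03 ± 0.23. Osteoclast markers fell for 5 of 7 (7 adjusted over the list alone), including Car2 (-2.32 ± 0.47), Tcirg1 (-0.69 ± 0.20) and Atp6v0d2 (-1.65 ± 0.48). These 2 bone lists had camera adjusted p = 6.08e-05 and 3.07e-04, and adjusted p = 0.390 and 0.377 with an estimated correlation.

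The endothelial, macrophage and synovial fibroblast lists were also called lower at 2 days, with 3 of 10, 5 of 17 and 4 of 15 markers passing (adjusted p = 0.419, 0.589 and 0.594 with an estimated correlation). Adjusted over the list alone 7 endothelial markers fell, and over all genes those that fell were Tie1 (-1.30 ± 0.33), Cdh5 (-0.78 ± 0.21) and Flt1 (-1.002 ± 0.32), while Esam at -0.71 ± 0.24 did not pass. Of the macrophage markers 5 fell adjusted over the list alone, and their mean was -0.11, -1.12 and -0.95 on the 3 arrays, with Tyrobp at -1.78 ± 0.36, Laptm5 at -2.21 ± 0.47, Cd68 at -1.51 ± 0.40 and Lyz2 at -2.13 ± 0.59. Of the synovial and tendon fibroblast markers, whose mean was 0.06, -0.55 and -0.43 on these arrays, 5 fell adjusted over the list alone, among them Pdpn (-0.56 ± 0.14), Fap (-0.45 ± 0.13) and the type I collagen genes that the osteoblast list also holds. The endothelial, macrophage and synovial lists had camera adjusted p = 5.52e-04, 0.00364 and 0.0306. The skeletal muscle list had a median of -1.31 (camera adjusted p = 0.00122), yet none of its 20 members passed, by either adjustment: Acta1 was at -2.31 ± 0.80, Myl1 at -1.94 ± 0.76, Ckm at -2.14 ± 0.89 and Ttn at -2.24 ± 0.97. With an estimated correlation the muscle list had adjusted p = 0.589, and its mean per array ranged in controls from -0.96 to 1.17. Immediate early genes fell for 5 of 24 (7 fell and 1 rose adjusted over the list alone), including Myc (-0.80 ± 0.15), Egr1 (-1.55 ± 0.32), Nr4a2 (-0.77 ± 0.17) and Jun (-0.76 ± 0.21). The camera adjusted p was 0.00442 for this list and 0.00378 for cytosolic ribosomal proteins, with adjusted p = 0.532 and 0.619 with an estimated correlation. Of the 41 ribosomal protein genes 4 fell (Rps15 -0.58, Rpl38 -0.46, Rps24 -0.39 and Rpl32 -0.47), Rps3 rose (0.51 ± 0.17), and none passed adjusted over the list alone. The collagen assembly list leaned lower (9 fell and 5 rose of 28, and 10 and 5 adjusted over the list alone, camera adjusted p = 0.0300). Its adjusted p = 0.594 with an estimated correlation. The procollagen peptidases Adamts3 (-1.56 ± 0.17) and Adamts14 (-1.43 ± 0.16) and the crosslinking enzyme Loxl4 (-1.88 ± 0.21) fell, and Tll1 rose by 1.46 ± 0.15.

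The 9 lists called higher at 2 days held stress, hormone, signalling, energy and matrix synthesis genes, with part of the members of each passing and none called with an estimated correlation (lowest adjusted p = 0.336). Of the heat shock and oxidative stress genes 13 of 26 rose (14 rose and 1 fell adjusted over the list alone), with the chaperones Hspb8 at 1.90 ± 0.25, Hsph1 at 1.84 ± 0.25 and Hsp90aa1 at 1.04 ± 0.17, and extracellular superoxide dismutase Sod3 at 0.62 ± 0.12. Glucocorticoid-responsive genes rose for 6 of 14 (7 adjusted over the list alone), with the kinase Sgk1 at 0.71 ± 0.16 and the sulfotransferase Sult1a1 at 1.19 ± 0.15 beside Fkbp5 and Zbtb16. Clock genes rose for 6 of 14 (8 adjusted over the list alone), including the repressors Bhlhe41 (0.94 ± 0.13), Cry2 (1.15 ± 0.17), Nr1d1 (0.70 ± 0.12) and Per2 (0.68 ± 0.15). These 3 lists had camera adjusted p = 6.90e-04, 8.80e-04 and 0.00160, each with adjusted p = 0.336 with an estimated correlation. In the hypoxia list 10 of 21 rose (13 adjusted over the list alone, camera adjusted p = 5.21e-05), with adrenomedullin (Adm) at 2.11 ± 0.34, Ankrd37 at 0.71 ± 0.12, P4ha2 at 0.72 ± 0.12 and Higd1a at 0.70 ± 0.13. In the TGF-beta and BMP list 11 of 34 rose and 2 fell (11 and 2 adjusted over the list alone, camera adjusted p = 0.00122). Both lists had adjusted p = 0.336 with an estimated correlation. Id2 rose by 0.91 ± 0.11, the co-receptor Tgfbr3 by 1.12 ± 0.13 and the BMP antagonists Grem1 and Chrdl2 by 1.85 ± 0.23 and 1.89 ± 0.34. Endoplasmic reticulum folding genes rose for 11 of 28 and 1 fell (16 and 2 adjusted over the list alone), with Hspa5 at 0.75 ± 0.11, Dnajb9 at 0.82 ± 0.13, Hyou1 at 1.01 ± 0.16 and Manf at 0.85 ± 0.14. Glycolysis genes rose for 7 of 21 and 1 fell (9 and 1 adjusted over the list alone), with Pfkfb3 at 1.19 ± 0.18, Hk2 at 1.36 ± 0.24, Ldha at 0.57 ± 0.13 and Pfkp at 0.69 ± 0.16. The folding and glycolysis lists had camera adjusted p = 3.07e-04 and 0.00730, and adjusted p = 0.342 and 0.390 with an estimated correlation. Proteoglycan and hyaluronan synthesis genes rose for 11 of 33 and 1 fell (11 and 1 adjusted over the list alone), led by Chst3 (1.32 ± 0.15), Csgalnact2 (1.18 ± 0.16), Xylt1 (0.84 ± 0.12) and Ugp2 (0.85 ± 0.16). Chondrocyte regulators rose for 7 of 18 and 2 fell (9 and 2 adjusted over the list alone), with Sox6 at 0.86 ± 0.13, Gli2 at 0.81 ± 0.12, Foxo1 at 0.94 ± 0.19 and Foxa3 at 0.48 ± 0.10. These lists had camera adjusted p = 0.0104 and 0.0232, and adjusted p = 0.452 and 0.390 with an estimated correlation.

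Of the cartilage genes fixed in advance, type II collagen (Col2a1) fell at 2 days (-0.48 ± 0.14, adjusted p = 0.0256), lubricin (Prg4) rose (0.40 ± 0.09, adjusted p = 0.00930), and aggrecan (Acan) at 0.26 ± 0.14 and link protein (Hapln1) at 0.04 ± 0.11 did not pass. The collagenase Mmp13 fell (-2.72 ± 0.76), stromelysin Mmp3 rose (1.05 ± 0.25) and cyclooxygenase Ptgs2 fell (-1.22 ± 0.30). Ugdh, which makes the UDP-glucuronate of glycosaminoglycans, rose by 0.58 ± 0.13, the sulfate donor enzyme Papss2 by 0.77 ± 0.16, Vegfa by 0.44 ± 0.14 and Hif1a by 0.51 ± 0.12. Col10a1 (0.10 ± 0.37), Adamts5 (0.23 ± 0.18), Timp3 (0.33 ± 0.15), Il1b (0.14 ± 0.10), Nos2 (-0.29 ± 0.16) and Has2 (0.16 ± 0.09) did not pass. Comp and Sox9 were not analysed here. The cartilage matrix list did not pass (7 of 27 higher and 9 lower, 8 and 10 adjusted over the list alone, camera adjusted p = 0.435). Nor did the lists of sterol synthesis (0.0693), inflammation (0.141), matrix proteases and their inhibitors (0.156), smooth muscle (0.273), TCA cycle (0.435), cytoskeleton (0.435), oxidative phosphorylation (0.449), fatty acid oxidation (0.459), interferon response (0.461), adipocyte (0.640), hypertrophy (0.704) or Wnt, Igf and Fgf (0.861), with camera adjusted p in brackets. In the adipocyte, interferon and hypertrophy lists the median and the mean differed in sign (0.03 and -0.15, -0.04 and 0.01, 0.05 and -0.25), and the camera direction was down for each. In every list called in the 6 comparisons the median, the mean and camera had the same sign. In all, limma called 2914 genes at 2 days, 1666 higher and 1248 lower, and 567 of them changed at least 2-fold. At an unadjusted p under 0.05 with a fold of 2 the balance turned, with 185 higher and 416 lower. The 3 exercised and 3 control arrays did not overlap at 36.8% of all genes, where chance gives 10%. Quantile normalization of the deposited values once more, which stretches the deviations of the controls by construction, left 765 calls, 434 higher and 331 lower. Of the genes that the rule fixed in advance named and that have values above, it ended the calls of Htr1b, Serpina1, Fam111a, Ngp, S100a9, Ahsp, Foxa3, Dnajb9, Ldha, Pfkp, Adm, Higd1a, Egr1, Nr4a2, Jun, Sod3, Bhlhe41, Per2, Aurkb, Rps15, Rpl38, Rps24, Rpl32, Car2, Tcirg1, Atp6v0d2, Epb42, Hemgn, Rhag, Prtn3, Ctsg, Rag1, Dntt, Cd79b, Cd68, Lyz2, Fap, Tie1, Cdh5, Col2a1, Prg4, Mmp3, Ptgs2, Vegfa and Hif1a, and of no list. Each of these gene changes kept its sign, for example Adm at 2.38, Serpina1 at 2.00, Ngp at -2.12 and Rpl38 at -0.28 after that normalization. Here and below, a call lost in that setting can come from the stretched controls, from a smaller change, or from both. Most changes that lost their call were smaller after it, for example Mmp3 at 0.92 against 1.05 and Ptgs2 at -0.95 against -1.22. Adm was an exception. The count was 1844 without control replicate 2, 1737 without the second rat and 1535 without the third rat of the 2-day group. Below, brackets name the array whose absence gave the highest adjusted p, and other arrays may end the same call. Leaving out 1 array ended the calls of Htr1b, Fam111a, S100a9, Pdpn, Tie1, Col2a1, Ptgs2 and Rpl32 (2-day replicate 3), of Ngp, Jun, Tcirg1, Atp6v0d2, Cd68, Lyz2, Fap, Cdh5, Flt1, Mmp13, Vegfa and the synovial list (2-day replicate 2), and of Rps15 and the collagen assembly list (control replicate 1). It also ended those of Rpl38, Rps24 and the chondrocyte regulator and muscle lists (control replicate 2) and of the proteoglycan and ribosomal lists (2-day replicate 1).

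**Figure D2:**
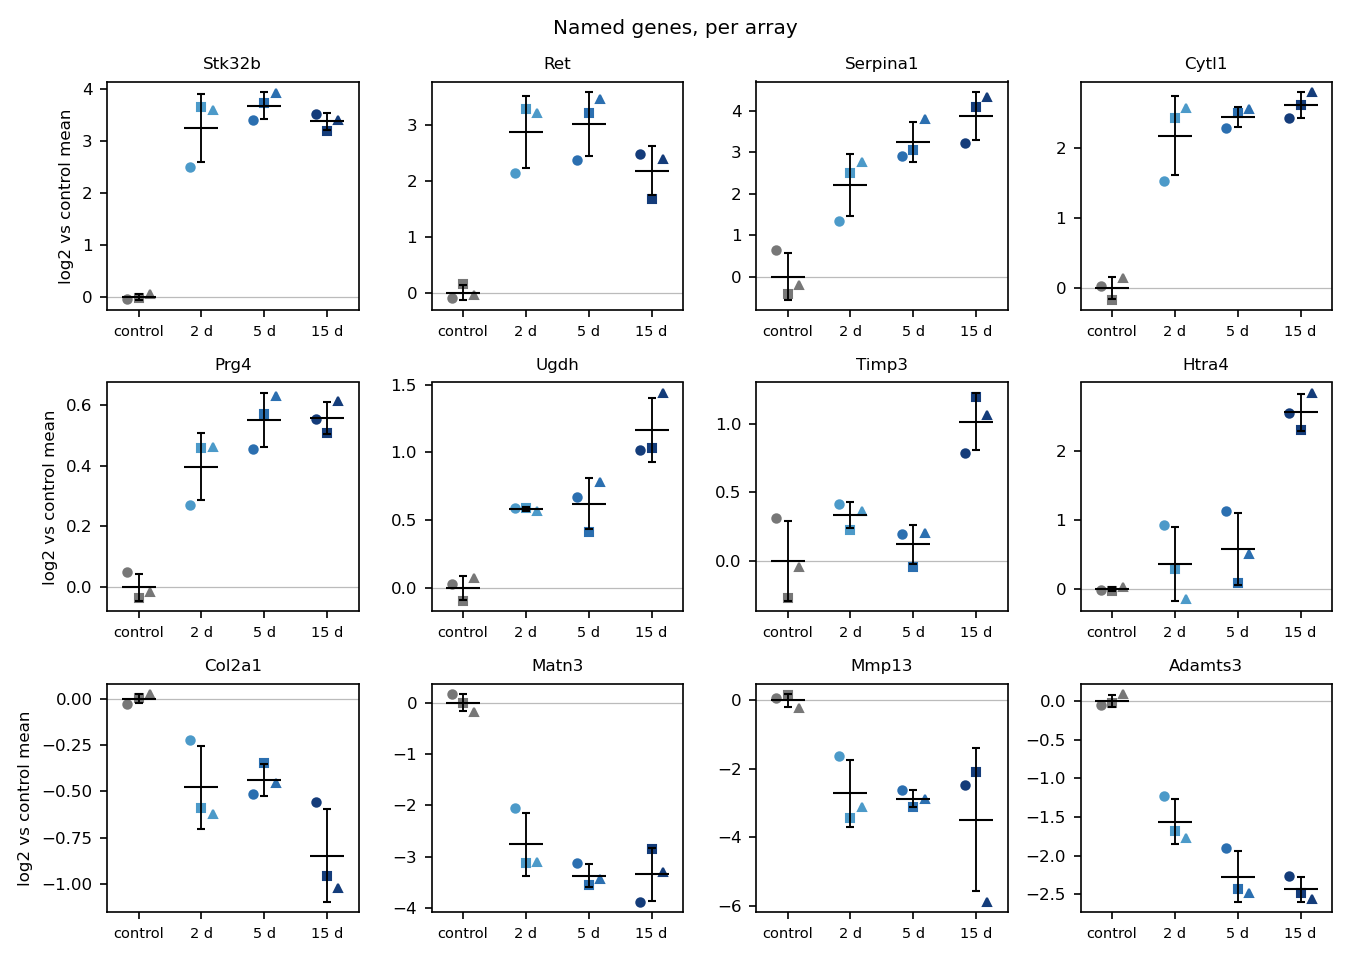
Log2 values relative to the control mean (vertical axes) of 12 named genes in the 4 groups (horizontal axes). Points are arrays of single rats (circle, square and triangle for replicates 1, 2 and 3), and bars are the mean with SD, n = 3. Stk32b averages 3.24, 3.68 and 3.37 after 2, 5 and 15 days, and Matn3 -2.76, -3.37 and -3.34.

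After 5 days camera called 10 lists higher and 13 lower than in controls, and none with an estimated correlation (lowest adjusted p = 0.313). The lower lists included the cell cycle (24 of 26 genes passing), lymphoid cells (8 of 15) and osteoblasts (6 of 13), and the higher ones heat shock (12 of 26), the glucocorticoid response (7 of 14) and the clock (7 of 14, with Npas2 lower). Stk32b showed the largest rise (3.68 ± 0.25, 12.8-fold, adjusted p = 1.78e-05), followed by Serpina1 (3.26 ± 0.40), Ret (3.01 ± 0.33), Htr1b (2.89 ± 0.72), Eml5 (2.71 ± 0.27) and Fkbp5 (2.65 ± 0.36). Zbtb16 (2.61 ± 0.28), the small heat shock protein Hspb1 (2.57 ± 0.40), P2rx5 (2.50 ± 0.40) and Cytl1 (2.44 ± 0.22) completed the 10 largest rises. The largest falls were in Fam111a (-3.92 ± 0.82, 15.1-fold lower), Mmp9 (-3.67 ± 0.69), Matn3 (-3.37 ± 0.29, 10.3-fold lower, adjusted p = 5.75e-05), Car1 (-3.16 ± 0.44) and Ngp (-3.12 ± 0.95). H1f1 (-2.91 ± 0.33), Mmp13 (-2.88 ± 0.76), Mpo (-2.84 ± 0.48), the carboxypeptidase Cpz (-2.80 ± 0.35) and S100a9 (-2.75 ± 0.73) followed.

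At 5 days 24 of 26 cell cycle genes fell (25 adjusted over the list alone, camera adjusted p = 1.39e-21), among them Ttk (-1.33 ± 0.11), Ccnb2 (-1.92 ± 0.18), the replication licensing factor Mcm5 (-1.49 ± 0.16) and Kif20a (-1.43 ± 0.15). Lymphoid markers fell for 8 of 15 (8 adjusted over the list alone, camera adjusted p = 1.27e-05), with Rag1 at -1.54 ± 0.19 and Dntt at -1.46 ± 0.22. Both lists had adjusted p = 0.313 with an estimated correlation. Granulocyte markers fell for 13 of 17 (14 adjusted over the list alone), with Elane at -2.29 ± 0.25 and Fcnb at -2.20 ± 0.33, and erythroid markers for 7 of 11 (10 adjusted over the list alone), with Epb42 at -1.41 ± 0.21, Hemgn at -2.05 ± 0.33 and Ahsp at -2.64 ± 0.51. Their camera adjusted p = 2.96e-08 and 7.79e-06, and adjusted p = 0.325 and 0.330 with an estimated correlation. Endothelial markers fell for 7 of 10 (10 adjusted over the list alone), osteoblast and osteocyte markers for 6 of 13 (9 alone) and osteoclast markers for 5 of 7 (7 alone). The camera adjusted p of these 3 lists was 5.23e-05, 9.77e-05 and 9.77e-05, and adjusted p = 0.363, 0.420 and 0.348 with an estimated correlation. Cdh5 was at -0.95 ± 0.21, Tie1 at -1.43 ± 0.33, Ifitm5 at -1.73 ± 0.15, the osteocyte protein Dmp1 at -1.84 ± 0.42, Tcirg1 at -1.01 ± 0.20 and Atp6v0d2 at -2.05 ± 0.48. Synovial fibroblast markers fell for 5 of 15 (5 adjusted over the list alone), with Pdpn at -0.88 ± 0.14 and Thy1 at -0.91 ± 0.24, and macrophage markers for 5 of 17 (5 alone), with Laptm5 at -2.14 ± 0.47 and Cd68 at -1.64 ± 0.40. Their camera adjusted p = 0.0115 and 0.0118, and adjusted p = 0.546 and 0.557 with an estimated correlation. The skeletal muscle list had a median of -1.69 (camera adjusted p = 2.25e-04), with 1 of 20 members lower (Myl1 -2.56 ± 0.76) and none adjusted over the list alone. Immediate early genes fell for 5 of 24 (8 fell and 1 rose adjusted over the list alone, camera adjusted p = 0.00697), with Nr4a2 at -0.93 ± 0.17, Myc at -0.73 ± 0.15, Egr1 at -1.51 ± 0.32 and Egr3 at -0.59 ± 0.18. The muscle and immediate early lists both had adjusted p = 0.546 with an estimated correlation. Ribosomal protein genes fell for 4 of 41 (none adjusted over the list alone), and collagen assembly genes fell for 9 and rose for 4 of 28 (11 and 4 alone). Their camera adjusted p = 0.00697 and 0.0156, and adjusted p = 0.603 and 0.557 with an estimated correlation. Adamts3 was at -2.27 ± 0.17 and Loxl4 at -2.30 ± 0.21.

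Of the glucocorticoid-responsive genes 7 of 14 rose at 5 days (10 rose and 1 fell adjusted over the list alone, camera adjusted p = 1.93e-05), with Sult1a1 at 1.54 ± 0.15 and Sgk1 at 0.99 ± 0.16. Heat shock and oxidative stress genes rose for 12 of 26 (15 adjusted over the list alone, camera adjusted p = 1.04e-04), with Hspb8 at 2.08 ± 0.25, Hsph1 at 1.73 ± 0.25 and Sod3 at 0.93 ± 0.12. Both lists had adjusted p = 0.313 with an estimated correlation. Clock genes rose for 7 of 14 and 1 fell (7 and 1 adjusted over the list alone), with Per2 at 1.51 ± 0.15, Cry1 at 1.60 ± 0.22, Cry2 at 1.31 ± 0.17 and Bhlhe41 at 0.99 ± 0.13. Endoplasmic reticulum folding genes rose for 11 of 28 and 1 fell (14 and 2 alone), with Hspa5 at 0.73 ± 0.11 and Hsp90b1 at 0.48 ± 0.09, and the transcription factor Creb3l1 at -1.18 ± 0.17. The clock and folding lists had camera adjusted p = 4.21e-04 and 2.37e-04, and adjusted p = 0.325 and 0.348 with an estimated correlation. TGF-beta and BMP genes rose for 10 of 34 and 2 fell (11 and 3 alone), among them Tgfbr3 (1.01 ± 0.13), Grem1 (1.38 ± 0.23) and Tgfbi (1.17 ± 0.20). Chondrocyte regulators rose for 10 of 18 and 2 fell (the same numbers alone), with Sox6 at 0.84 ± 0.13, Foxo1 at 0.95 ± 0.19 and the hedgehog target Gli1 at -0.52 ± 0.11. Their camera adjusted p = 0.00259 and 0.0115, and adjusted p = 0.348 and 0.363 with an estimated correlation. Proteoglycan synthesis genes rose for 11 of 33 and 2 fell (12 and 2 alone), with Chst3 at 1.39 ± 0.15 and Csgalnact2 at 1.35 ± 0.16, and hypoxia genes rose for 3 of 21 (3 alone), namely Adm (1.56 ± 0.34), P4ha2 (0.59 ± 0.12) and Egln3 (1.13 ± 0.32). Glycolysis genes rose for 4 of 21 and 1 fell (5 and 1 alone), with Pgk1 at 0.64 ± 0.15 and Pkm at 0.54 ± 0.13. These 3 lists had camera adjusted p = 0.0327, 0.0137 and 0.0493, each with adjusted p = 0.546 with an estimated correlation. Sterol and fatty acid synthesis genes rose for 9 of 25 and 3 fell (the same numbers alone, camera adjusted p = 0.0493), with Pmvk at 0.66 ± 0.11, Hsd17b7 at 0.53 ± 0.09, Msmo1 at 0.64 ± 0.12 and the desaturase Fads1 at -1.43 ± 0.21. That list had adjusted p = 0.557 with an estimated correlation.

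In the cartilage panel at 5 days Col2a1 fell (-0.44 ± 0.14, adjusted p = 0.0380), Prg4 rose (0.55 ± 0.09, adjusted p = 0.00148), and Mmp3 (1.14 ± 0.25), Ugdh (0.62 ± 0.13), Papss2 (0.70 ± 0.16) and Ldha (0.48 ± 0.13) rose. Ptgs2 fell (-1.46 ± 0.30). Acan (0.38 ± 0.14), Hapln1 (0.11 ± 0.11), Col10a1 (0.83 ± 0.37), Adamts5 (0.07 ± 0.18), Timp3 (0.12 ± 0.15), Il1b (0.10 ± 0.10), Nos2 (-0.06 ± 0.16), Vegfa (0.31 ± 0.14), Has2 (-0.11 ± 0.09) and Hif1a (0.29 ± 0.12) did not pass. The cartilage matrix list had 7 members higher and 8 lower of 27 (9 and 13 adjusted over the list alone) and did not pass (camera adjusted p = 0.481). The hypertrophy list had a median of 0.11 and a mean of -0.15, with the camera direction up (adjusted p = 0.697). In all, limma called 2800 genes at 5 days, 1468 higher and 1332 lower, and 608 of them changed at least 2-fold. At an unadjusted p under 0.05 with a fold of 2, 212 were higher and 445 lower. Slightly more genes were lower than higher without 5-day replicate 1 (1247 higher and 1271 lower), with only these 2 groups in the fit (1423 and 1437), and in 2 settings chosen after seeing the data, without the muscle-rich arrays (936 and 957) and without the first arrays of 2 and 5 days (1313 and 1347). The arrays did not overlap at 37.7% of genes (10% by chance). Quantile normalization once more, with its stretched controls, left 804 calls, 456 higher and 348 lower. Of the genes that the rule fixed in advance named and that have values above, it ended the calls of Fam111a, Ngp, S100a9, Pgk1, Pkm, Ldha, Adm, Egln3, Nr4a2, Egr1, Egr3, Cry1, Myl1, Atp6v0d2, Epb42, Hemgn, Ahsp, Rag1, Dntt, Cd68, Thy1, Col2a1 and Mmp3, and of the sterol list. Each of these gene changes kept its sign, for example Adm at 1.85, Cry1 at 1.32, Ngp at -2.31 and Egr3 at -0.43 after that normalization. The count was 1797 without the second and 1719 without the third 5-day rat. Of the 108 named gene calls at 5 days 23 ended without 1 array, and not all of them are listed here. Leaving out 1 array ended the calls of Htr1b, Pgk1, Pkm, Egr3, Atp6v0d2, Cd68, Papss2 and the glycolysis and macrophage lists (5-day replicate 3), of Mmp13, S100a9, Ldha and Lyz2 (5-day replicate 2), and of Col2a1 (5-day replicate 1). It also ended those of Ngp, Egln3, Myl1 and the proteoglycan and sterol lists (control replicate 2), of Thy1 and the collagen assembly list (control replicate 1), and of the hypoxia and synovial lists (control replicate 3).

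After 15 days camera called 8 lists higher and 9 lower, and none with an estimated correlation (lowest adjusted p = 0.342). The lower lists included granulocytes (13 of 17 markers passing), erythroid cells (10 of 11) and osteoblasts (10 of 13), and the higher ones heat shock (16 of 26), the clock (8 of 14), TGF-beta and BMP (12 of 34), proteoglycan synthesis (14 of 33, with 4 lower) and the TCA cycle (8 of 21, with 1 lower). Serpina1 led the rises (3.88 ± 0.40, 14.7-fold, adjusted p = 6.39e-05), with Stk32b (3.37 ± 0.25), the chemokine Cxcl13 (3.11 ± 0.51), the receptor Il17rb (2.80 ± 0.21) and Cytl1 (2.61 ± 0.22). Spp2 (2.60 ± 0.37), the serine protease Htra4 (2.56 ± 0.27), the proteoglycan versican (Vcan, 2.51 ± 0.32), Eml5 (2.34 ± 0.27) and the lipopolysaccharide-binding protein Lbp (2.33 ± 0.37) followed. Mmp9 led the falls (-4.52 ± 0.69, 22.9-fold lower, adjusted p = 6.82e-04), with H1f1 (-3.79 ± 0.33), Mpo (-3.76 ± 0.48), Ngp (-3.72 ± 0.95), Ahsp (-3.65 ± 0.51) and S100a9 (-3.58 ± 0.73). The osteocyte endopeptidase Phex (-3.54 ± 0.51), Car1 (-3.54 ± 0.44), topoisomerase Top2a (-3.49 ± 0.36) and Mmp13 (-3.49 ± 0.76) completed the 10 largest falls.

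Of the 26 cell cycle genes 24 fell and 1 rose at 15 days (25 and 1 adjusted over the list alone), with Ccnb2 at -2.17 ± 0.18, Aurkb at -1.74 ± 0.16, Bub1 at -1.74 ± 0.16 and Pcna, the gene that rose, at 0.51 ± 0.17. Granulocyte markers fell for 13 of 17 (13 adjusted over the list alone), with Elane at -2.67 ± 0.25 and Fcnb at -2.82 ± 0.33, erythroid markers for 10 of 11 (11 alone), with Hemgn at -2.61 ± 0.33 and Rhag at -2.16 ± 0.31, and lymphoid markers for 7 of 15 (8 alone), with Rag1 at -1.71 ± 0.19. These 4 lists had camera adjusted p = 5.31e-22, 8.37e-10, 8.08e-09 and 5.10e-05, each with adjusted p = 0.342 with an estimated correlation. Osteoblast and osteocyte markers fell for 10 of 13 (11 adjusted over the list alone), with Smpd3 at -2.29 ± 0.25, Ifitm5 at -1.71 ± 0.15 and Mepe at -1.87 ± 0.33. All 7 measured osteoclast markers fell by either adjustment, among them Car2 (-3.32 ± 0.47), Atp6v0d2 (-2.84 ± 0.48) and Tcirg1 (-0.93 ± 0.20). The bone lists had camera adjusted p = 2.53e-08 and 1.59e-05, and adjusted p = 0.351 and 0.360 with an estimated correlation. Endothelial markers fell for 2 of 10 (3 adjusted over the list alone), Cdh5 (-0.89 ± 0.21) and Cldn5 (-0.57 ± 0.16), ribosomal protein genes for 5 of 41 (3 alone), such as Rpl13 (-0.58 ± 0.16). Collagen assembly genes fell for 9 and rose for 4 of 28 (10 and 5 alone), with Adamts3 at -2.44 ± 0.17, Loxl4 at -2.19 ± 0.21, Bmp1 at -1.31 ± 0.13 and Tll1 at 1.46 ± 0.15. The endothelial, ribosomal and collagen assembly lists had camera adjusted p = 0.00567, 0.00141 and 0.00516, and adjusted p = 0.602, 0.634 and 0.588 with an estimated correlation. The macrophage (0.467), synovial fibroblast (0.394), skeletal muscle (0.467), immediate early (0.721), hypoxia (0.0914), chondrocyte regulator (0.169) and sterol (0.123) lists did not pass at 15 days, with camera adjusted p in brackets. The mean of the macrophage list was 0.18, 0.30 and -0.94 on the 3 arrays, and that of the muscle list -0.42, 1.80 and -1.69.

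**Figure D3:**
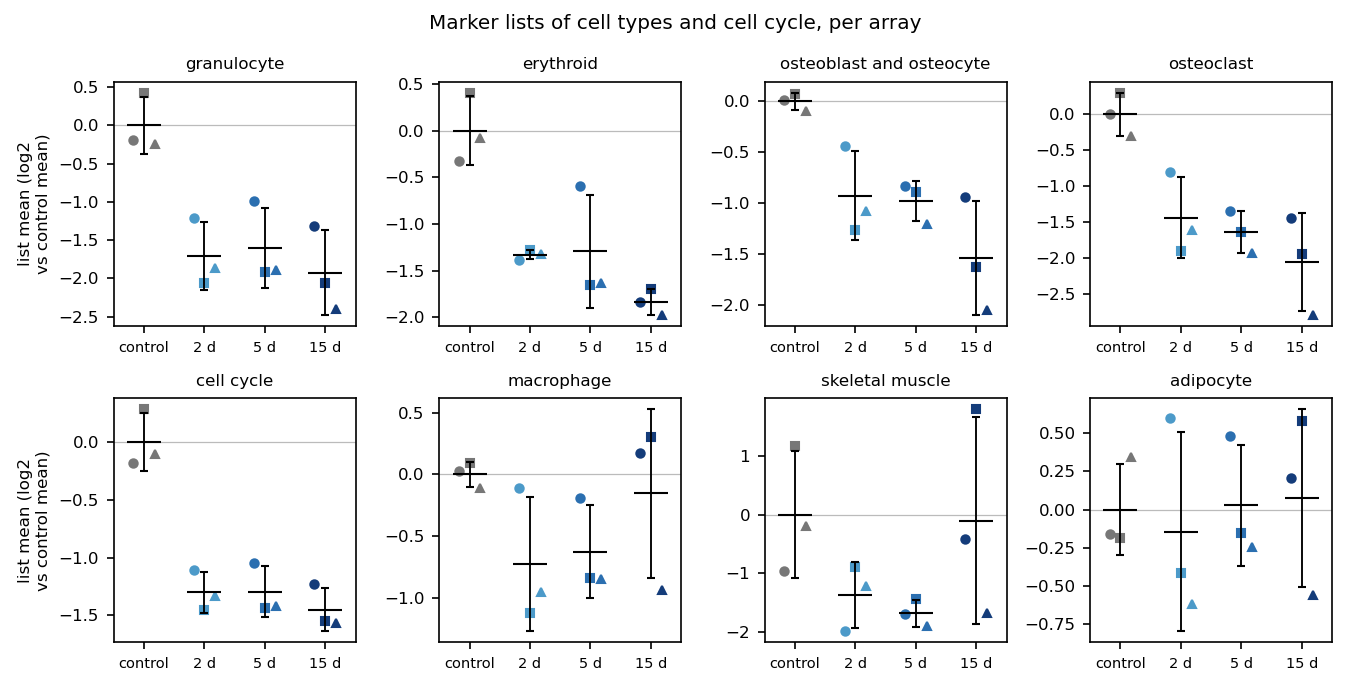
Mean log2 value relative to controls (vertical axes) of marker lists of 7 cell types and of the cell cycle list in the 4 groups (horizontal axes). Points are arrays of single rats (circle, square and triangle for replicates 1, 2 and 3), and bars are the mean with SD, n = 3. The granulocyte mean lies between -2.40 and -0.99 on the 9 exercised arrays, while macrophage and muscle means vary widely within groups.

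Heat shock and oxidative stress genes rose for 16 of 26 at 15 days (17 adjusted over the list alone, camera adjusted p = 9.07e-06), with the superoxide dismutases Sod3 and Sod2 at 1.03 ± 0.12 and 0.81 ± 0.12 and the autophagy receptor Sqstm1 at 0.59 ± 0.10. That list had adjusted p = 0.342 with an estimated correlation. Glucocorticoid-responsive genes rose for 8 of 14 and clock genes for 8 of 14 (the same numbers adjusted over the list alone), with Sult1a1 at 1.51 ± 0.15, Sgk1 at 1.09 ± 0.16, Fkbp5 at 2.03 ± 0.36, Per2 at 1.22 ± 0.15 and Nr1d1 at 0.84 ± 0.12. Their camera adjusted p = 0.00262 and 0.00559, each with adjusted p = 0.376 with an estimated correlation. TGF-beta and BMP genes rose for 12 of 34 (15 rose and 1 fell adjusted over the list alone), with Tgfbr3 at 1.41 ± 0.13, activin (Inhba) at 0.94 ± 0.16, Bmp6 at 1.36 ± 0.25 and Bmp5 at 0.85 ± 0.16. TCA cycle genes rose for 8 of 21 and 1 fell (10 and 1 alone), with Mdh1 at 0.79 ± 0.09, Idh3b at 0.65 ± 0.13, Ogdh at 0.54 ± 0.12 and Pc at 0.58 ± 0.13. The TGF-beta and TCA lists had camera adjusted p = 0.00168 and 0.00516, and adjusted p = 0.360 and 0.461 with an estimated correlation. Proteoglycan synthesis genes rose for 14 of 33 and 4 fell (14 and 5 alone), led by Ugdh (1.17 ± 0.13), Csgalnact1 (0.94 ± 0.14) and the hyaluronan synthase Has1 (0.81 ± 0.13). Folding genes rose for 10 of 28 and 1 fell (12 and 1 alone), with Hspa5 at 0.78 ± 0.11 and Creb3l1 at -1.38 ± 0.17. Glycolysis genes rose for 7 of 21 and 1 fell (8 and 1 alone), with Hk2 at 1.33 ± 0.24, the glucose carrier Slc2a1 at 0.67 ± 0.15 and the lactate carrier Slc16a1 at -0.62 ± 0.17. These 3 lists had camera adjusted p = 0.0171, 0.00567 and 0.0127, and adjusted p = 0.588, 0.513 and 0.509 with an estimated correlation.

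**Figure D4:**
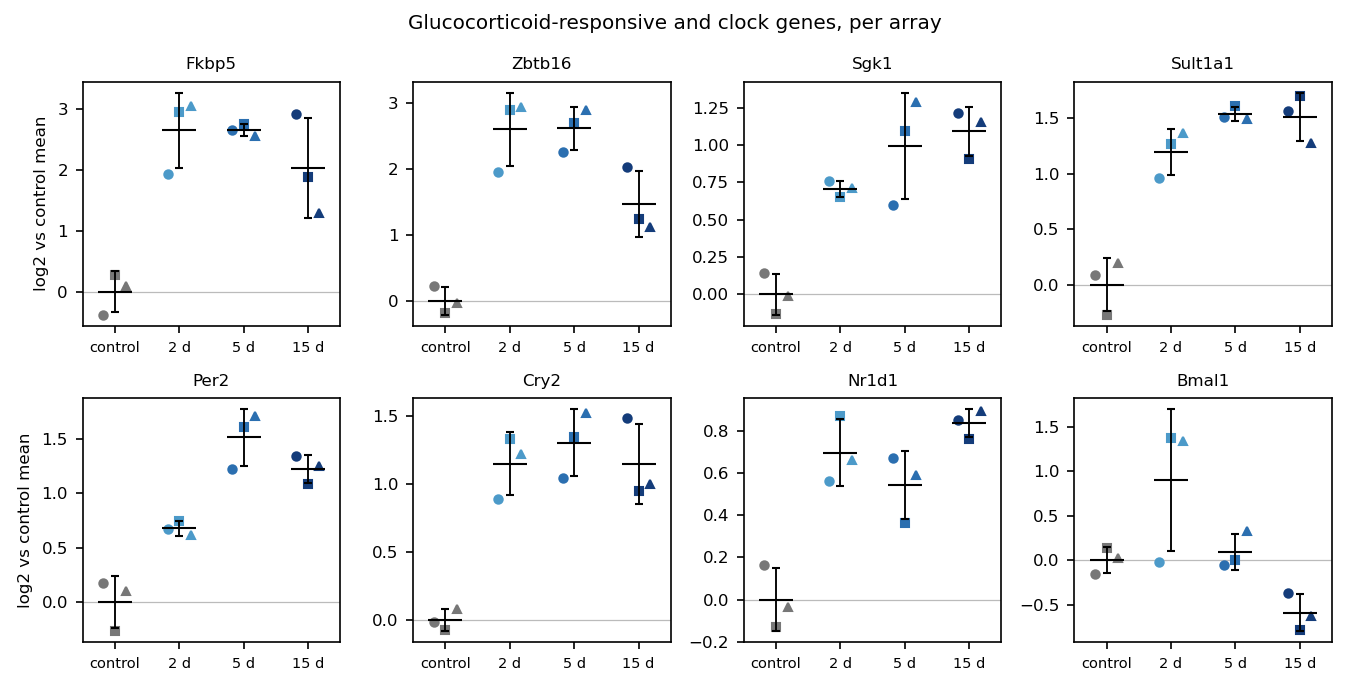
Log2 values relative to the control mean (vertical axes) of 4 glucocorticoid-responsive and 4 clock genes in the 4 groups (horizontal axes). Points are arrays of single rats (circle, square and triangle for replicates 1, 2 and 3), and bars are the mean with SD, n = 3. Per2 averages 0.68, 1.51 and 1.22 after 2, 5 and 15 days, while Bmal1 is spread at 2 days and lies below 0 on all 3 arrays at 15 days.

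In the cartilage panel at 15 days Col2a1 fell (-0.84 ± 0.14, adjusted p = 8.97e-04), as did Ptgs2 (-1.29 ± 0.30). Prg4 (0.56 ± 0.09), the metalloproteinase inhibitor Timp3 (1.01 ± 0.15, adjusted p = 5.35e-04), the aggrecanase Adamts5 (0.70 ± 0.18), Has2 (0.32 ± 0.09) and Ldha (0.43 ± 0.13) rose. Acan (0.25 ± 0.14), Hapln1 (0.04 ± 0.11), Col10a1 (0.85 ± 0.37), Mmp3 (0.42 ± 0.25), Il1b (0.19 ± 0.10), Nos2 (-0.32 ± 0.16), Vegfa (-0.11 ± 0.14), Papss2 (0.12 ± 0.16) and Hif1a (0.33 ± 0.12) did not pass. The cartilage matrix list had 8 members higher and 9 lower of 27 (9 and 11 adjusted over the list alone) and did not pass (camera adjusted p = 0.281). Median and mean differed in sign in the matrix protease and inhibitor list (0.16 and -0.25, camera up, adjusted p = 0.761) and the macrophage list (0.03 and -0.15, camera down). For the hypertrophy, smooth muscle and Wnt, Igf and Fgf lists the camera direction was opposite to the mean (-0.23, 0.01 and 0.04). In all, limma called 3251 genes at 15 days, 1949 higher and 1302 lower, and 639 of them changed at least 2-fold. At an unadjusted p under 0.05 with a fold of 2 the balance turned, with 253 higher and 402 lower. The arrays did not overlap at 35.6% of genes (10% by chance). Quantile normalization once more, with its stretched controls, left 678 calls at 15 days, 331 higher and 347 lower. Of the genes that the rule fixed in advance named and that have values above, it ended the calls of Ngp, Ahsp, S100a9, Car1, Slc2a1, Idh3b, Ogdh, Pc, Inhba, Bmp6, Bmp5, Sqstm1, Aurkb, Rpl13, Mepe, Atp6v0d2, Tcirg1, Rhag, Rag1, Cldn5, Adamts5, Timp3, Ptgs2, Ldha and Has2, and of no list. Each of these gene changes kept its sign, for example Timp3 at 0.80, Bmp6 at 0.96, Ngp at -2.16 and Atp6v0d2 at -1.79 after that normalization. Of the 89 named gene calls at 15 days 11 ended without 1 array, and not all of them are listed here. Leaving out 1 array ended the calls of Ngp, Adamts5 and Has2 (control replicate 2), of Slc16a1, Cldn5 and Ldha (control replicate 3), of Rpl13 and the endothelial list (15-day replicate 3), of the ribosomal list (15-day replicate 2), and of the proteoglycan, folding and glycolysis lists (15-day replicate 1). Over all 4 groups the moderated F-test of limma called 3226 genes, and 1919 without control replicate 2. Without the arrays with the highest muscle marker mean of the control and 15-day groups, chosen after seeing the data, the counts were 1848, 1893 and 1923 at 2, 5 and 15 days.

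The calls of the exercised groups overlapped. At 2 and 5 days 1187 genes were higher in both and 1038 lower in both, where independent lists of these sizes would share 171.3 and 116.4. At 2 and 15 days 1120 were higher in both and 891 lower (227.4 and 113.8 for independent lists), and at 5 and 15 days 1043 and 938 (200.4 and 121.5). In opposite directions there were 3 genes between 2 and 15 days, Cd48 (-0.40 and 0.38), Mrpl10 (-0.29 and 0.34) and Prdx6 (-0.28 and 0.40), and 1 between 5 and 15 days, Pdha1 (-0.27 and 0.28), named after their values were seen. Across genes, which are not independent replicates, the log2 fold changes correlated at r = 0.948 between 2 and 5 days, 0.836 between 2 and 15 days and 0.841 between 5 and 15 days. Simulated groups with no effect and the same controls gave r = 0.4998. The covariances were 0.186, 0.171 and 0.179, against 0.0126 in the simulation. The 3 controls are too few to give each comparison its own set of 2, so part of the excess in overlap may come from the shared controls.

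Between 5 and 2 days no gene passed (0 calls by limma, 530 at an unadjusted p under 0.05, and 3 with array weights). The genes with the smallest p were Per2 (0.84 ± 0.15), Kctd5 (0.52 ± 0.09), the ion channel Asic2 (1.02 ± 0.22), Pdzk1 (0.43 ± 0.10) and Mthfd1l (0.51 ± 0.12) among those higher at 5 days. Those lower were Pwwp3b (-0.59 ± 0.10), Rnd3 (-0.57 ± 0.10), Ankrd37 (-0.65 ± 0.12), the imprinted RNA H19 (-0.72 ± 0.15) and the homeobox gene Meox2 (-0.68 ± 0.14). None of these 10 passed, with adjusted p from 0.366 to 0.965. The hypoxia list was lower at 5 days (median -0.20, camera adjusted p = 8.45e-05) and the glucocorticoid list higher (median 0.24, camera adjusted p = 0.0110), each with adjusted p = 0.954 with an estimated correlation. No member of either list passed over all genes, and adjusted over the list alone 2 hypoxia members fell and no glucocorticoid member passed. Higd1a was at -0.48 ± 0.13, Car12 at -0.46 ± 0.18, Slc2a1 at -0.34 ± 0.15, Sult1a1 at 0.34 ± 0.15, Sgk1 at 0.29 ± 0.16, Cdkn1a at -0.33 ± 0.21 and the tyrosine aminotransferase Tat at 0.16 ± 0.11. Panel genes lay between -0.27 (Has2) and 0.73 (Col10a1), and none passed. The hypoxia call ended without 2-day replicate 2 and the glucocorticoid call without 2-day replicate 1 and after quantile normalization once more. The 2 groups did not overlap at 10.8% of genes, where chance gives 10%.

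From 5 to 15 days few genes passed, and their number and balance changed with single arrays, while no list was called with an estimated correlation (lowest adjusted p = 0.382). The largest rises were in Htra4 (1.98 ± 0.27, adjusted p = 0.0175), the integrin Itgb8 (1.502 ± 0.27), the chemerin receptor Cmklr2 (1.47 ± 0.20), Clec2dl1 (1.34 ± 0.24) and the aldo-keto reductase Akr1b8 (1.20 ± 0.13). Only 3 genes were lower, the citron kinase Cit (-1.78 ± 0.28), Rab27b (-0.71 ± 0.12) and the histone H2bc18 (-1.11 ± 0.19), while Ccdc68 (-0.78 ± 0.14) and Oxct2b (-0.89 ± 0.17) did not pass. The list of matrix proteases and their inhibitors was higher (median 0.24, 1 of 24 passing, and 7 higher and 1 lower adjusted over the list alone). The only member passing was an inhibitor, Timp3, which rose by 0.90 ± 0.15. The cathepsins Ctsl (0.75 ± 0.15) and Ctsb (0.53 ± 0.11) and Mmp19 (1.04 ± 0.21) did not pass. The immediate early list was higher (median 0.47, none of 24 passing over all genes and 8 adjusted over the list alone), with Nr4a2 at 0.79 ± 0.17, Jun at 0.94 ± 0.21, Atf3 at 2.00 ± 0.44 and Arc at 0.65 ± 0.16. Its mean on the 3 arrays of 15 days was 0.65, -0.36 and 0.06, and without the first of them the mean difference of 0.57 was 0.30. The TCA list was higher (median 0.16, 1 of 21 passing and 6 alone), with Pdha1 rising by 0.55 ± 0.09 and Sdhb (0.36 ± 0.09), Mdh1 (0.39 ± 0.09) and Cs (0.37 ± 0.10) not passing. These 3 lists had camera adjusted p = 0.00106, 5.07e-06 and 1.34e-04, each with adjusted p = 0.744 with an estimated correlation. The inflammation list was higher (median 0.15, 1 of 35 passing and 9 alone, camera adjusted p = 7.05e-04), with the adaptor Myd88 rising by 0.58 ± 0.10 and Irak3 (0.93 ± 0.18), Tnfrsf1a (0.63 ± 0.12) and Icam1 (0.60 ± 0.13) not passing. That list had adjusted p = 0.382 with an estimated correlation. The lists of oxidative phosphorylation (Cox6c 0.50 ± 0.12 and Cox5a 0.56 ± 0.16), cytoskeleton (Cav1 0.67 ± 0.17), skeletal muscle (Myl1 2.22 ± 0.76) and macrophages (Cd14 1.39 ± 0.29) were higher with no member passing, at camera adjusted p = 3.47e-04, 0.00509, 1.34e-04 and 0.0187. Lower with no member passing were the osteoblast (Omd -0.62 ± 0.20), erythroid (Sptb -0.61 ± 0.21), cell cycle (Bub1 -0.42 ± 0.16 and Pcna 0.53 ± 0.17) and granulocyte (Mpo -0.92 ± 0.48) lists, at camera adjusted p = 4.24e-04, 0.00106, 0.0197 and 0.0339. All 8 of these lists had adjusted p = 0.744 with an estimated correlation, and adjusted over the list alone 1 macrophage member and no other passed. Other panel genes did not pass, from -0.72 (Mmp3) to 0.64 (Adamts5). In all, limma called 33 genes, 30 higher and 3 lower, out of 2124 with an unadjusted p under 0.05, and the groups did not overlap at 19.7% of genes (10% by chance). Each named gene call ended without 5-day replicate 2 or 3, and list calls ended for oxidative phosphorylation and cytoskeleton (without 15-day replicate 1), muscle and macrophage (15-day replicate 2) and cell cycle, erythroid and granulocyte (5-day replicate 1). The count moved with each array left out: it was 21, 51 and 9 without control replicates 1, 2 and 3, and 164, 9 and 6 without those of 2 days. It was 56, 0 and 1 without those of 5 days, 184 (101 higher and 83 lower), 17 and 16 without those of 15 days, 0 after quantile normalization once more (which also ended the cell cycle and granulocyte list calls) and 1, a lower gene, with only these 2 groups in the fit. It was larger with array weights (374) and a trended robust prior (117).

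From 2 to 15 days the asporin gene Aspn (2.21 ± 0.46), Htra4 (2.19 ± 0.27, adjusted p = 0.00718), Lrrn4cl (2.19 ± 0.38), Crip1 (2.03 ± 0.36) and Spp2 (1.89 ± 0.37) showed the largest rises. The largest falls were in type IX collagen Col9a1 (-1.53 ± 0.33, adjusted p = 0.0498), the clock activator Bmal1 (-1.49 ± 0.29), the kinesin Kif3c (-1.21 ± 0.18), Filip1 (-1.05 ± 0.20) and Pfkfb3 (-0.999 ± 0.18). The inflammation list was higher (5 of 35 rose, 8 adjusted over the list alone, camera adjusted p = 1.10e-04), with the receptor Tlr4 at 0.84 ± 0.15, Tnf at 0.54 ± 0.10, Icam1 at 0.68 ± 0.13 and Myd88 at 0.53 ± 0.10. That list had adjusted p = 0.181 with an estimated correlation. Single members also rose in the lists of immediate early genes (Jun 1.14 ± 0.21), matrix proteases and inhibitors (the plasminogen activator Plat 0.71 ± 0.13), cytoskeleton (Tuba1a 0.73 ± 0.15) and macrophages (Cd14 1.35 ± 0.29), at camera adjusted p = 1.75e-06, 0.00234, 8.78e-04 and 0.00225. Each of these 4 lists had adjusted p = 0.724 with an estimated correlation, and adjusted over the list alone 9, 8, 1 and 1 members rose. With no member passing over all genes, the oxidative phosphorylation (Ndufs7 0.48 ± 0.11), TCA (Idh3b 0.53 ± 0.13), heat shock (Nfe2l2 0.45 ± 0.11) and muscle (Acta1 1.88 ± 0.80) lists were higher, at camera adjusted p = 1.10e-04, 8.78e-04, 0.0413 and 9.02e-04. Each had adjusted p = 0.724 with an estimated correlation, and 10, 5, 3 and 0 members rose adjusted over the list alone. The hypoxia list was lower, with Ankrd37 passing at -0.70 ± 0.12 and Adm (-1.29 ± 0.34) and Vegfa (-0.55 ± 0.14) not passing, at camera adjusted p = 9.02e-04 (6 fell and 1 rose adjusted over the list alone). The osteoblast (Smpd3 -0.94 ± 0.25), erythroid (Sptb -0.74 ± 0.21) and osteoclast (Atp6v0d2 -1.19 ± 0.48) lists were lower with no member passing over all genes, at camera adjusted p = 3.80e-04, 0.00251 and 0.0319. These 4 lists had adjusted p = 0.724 with an estimated correlation, and 5 osteoblast, 2 erythroid and no osteoclast markers fell adjusted over the list alone. The cell cycle list (Bub1 -0.43 ± 0.16 and Pcna 0.45 ± 0.17) and the collagen assembly list (Adamts3 -0.88 ± 0.17, the only member passing over all genes) were lower at camera adjusted p = 0.0335 and 0.0413. Both had adjusted p = 0.829 with an estimated correlation, and adjusted over the list alone no cell cycle member passed while 2 collagen assembly genes fell and 1 rose. No panel gene passed, with Timp3 at 0.68 ± 0.15, Ugdh at 0.58 ± 0.13 and Papss2 at -0.65 ± 0.16. In all, limma called 130 genes, 93 higher and 37 lower, out of 2048 with an unadjusted p under 0.05, and the groups did not overlap at 17.8% of genes (10% by chance). Each named gene call ended without 2-day replicate 2 or 3, and list calls ended for collagen assembly, heat shock, cell cycle and osteoblast (without 2-day replicate 1), cytoskeleton (15-day replicate 1), muscle and macrophage (15-day replicate 2) and osteoclast (15-day replicate 3). The count was 301, 7 and 0 without 2-day replicates 1, 2 and 3, and 289, 58 and 38 without those of 15 days. Without 15-day replicate 1 the balance turned, with 129 higher and 160 lower. It was 38 without control replicate 3, 69 and 34 without 5-day replicates 2 and 3, 0 after quantile normalization once more (which also ended the collagen assembly, heat shock, cell cycle, osteoclast and erythroid list calls) or with only these 2 groups in the fit, 621 with array weights and 169 with a trended robust prior.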

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

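The tests of the explanations weighed here were chosen after the results were seen, while the counts over other splits of the arrays were planned. The differences between durations that passed their test are given first, as mean log2 differences for lists and as log2 differences for genes. Only genes that the rule fixed in advance named in any comparison are given. The 33 and 130 genes called from 5 and from 2 to 15 days are therefore not all listed. From 2 to 5 days the hypoxia list differed by -0.19 (-0.11) and the glucocorticoid list by 0.20 (0.0654), where brackets here and below hold the value without the 1 array whose absence gave the highest camera p. From 5 to 15 days the differences were 0.21 (0.11) for matrix proteases and inhibitors, 0.24 (0.22) for inflammation, 0.19 (0.14) for the TCA cycle, 0.17 (0.12) for oxidative phosphorylation, 0.17 (0.0912) for the cytoskeleton, 0.57 (0.30) for immediate early genes, 1.58 (0.63) for skeletal muscle and 0.47 (0.25) for macrophages. They were -0.15 (-0.0249) for the cell cycle, -0.56 (-0.31) for osteoblasts and osteocytes, -0.54 (-0.19) for erythroid cells and -0.33 (-0.0252) for granulocytes. From 2 to 15 days they were 0.14 (0.0173) for matrix proteases and inhibitors, 0.24 (0.22) for inflammation, 0.15 (0.10) for the TCA cycle, 0.17 (0.11) for oxidative phosphorylation, 0.19 (0.12) for the cytoskeleton, 0.56 (0.29) for immediate early genes, 0.13 (0.0383) for heat shock, 1.27 (0.32) for skeletal muscle and 0.57 (0.35) for macrophages. They were -0.072 (-0.00373) for collagen assembly, -0.26 (-0.18) for hypoxia, -0.15 (-0.0549) for the cell cycle, -0.61 (-0.37) for osteoblasts and osteocytes, -0.62 (-0.26) for osteoclasts and -0.50 (-0.51) for erythroid cells. None of these list differences passed with an estimated correlation, where the lowest adjusted p was 0.954 from 2 to 5 days, 0.382 from 5 to 15 days and 0.181 from 2 to 15 days.

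From 5 to 15 days Akr1b8 differed by 1.20, Clec2dl1 by 1.34, Cmklr2 by 1.47, Has1 by 0.90, Htra4 by 1.98, Itgb8 by 1.502, Meox2 by 0.83, Myd88 by 0.58, Pdha1 by 0.55, Pdpn by 1.05, Rnd3 by 0.63 and Timp3 by 0.90, while Cit differed by -1.78, H2bc18 by -1.11 and Rab27b by -0.71. From 2 to 15 days the higher ones among the named genes were Akr1b8 (1.16), Aspn (2.21), Cd14 (1.35), Clec2dl1 (1.21), Cmklr2 (1.66), Crip1 (2.03), Has1 (1.13), Htra4 (2.19), Icam1 (0.68), Il17rb (1.21), Itgb8 (1.46) and Jun (1.14). Others were Lrrn4cl (2.19), Myd88 (0.53), Pdpn (0.73), Plat (0.71), Spp2 (1.89), Tlr4 (0.84), Tnf (0.54) and Tuba1a (0.73). Lower were Adamts3 (-0.88), Ankrd37 (-0.70), Bmal1 (-1.49), Col9a1 (-1.53), Filip1 (-1.05), Gli2 (-0.61), H19 (-0.83), Id2 (-0.62), Kif3c (-1.21), Pfkfb3 (-0.999) and Pwwp3b (-0.53). Outside the analysed genes, 1041 of 5704 probe sets with no or several symbols (18.25%) passed the test over the 4 groups.

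The marrow, bone and cell cycle lists were called lower in all 3 exercised groups, and none with an estimated correlation (lowest adjusted p = 0.336, 0.313 and 0.342 at 2, 5 and 15 days). A shift of whole arrays left by the normalization is argued against, since it would move all genes alike. The median change of all genes was only 0.0131, 0.0114 and 0.0159 at 2, 5 and 15 days. The means of the granulocyte, erythroid, lymphoid, osteoblast, osteoclast and cell cycle lists lay below that of all genes by more than 3 SE in each exercised group. The fewest SE were for the erythroid list at 5 days (-1.28, SE 0.411). These lists were picked because camera had called them lower than other genes, so their distance restates that call, and only the medians carry the argument. For the granulocyte list at 15 days an unusual control array as the whole cause is also argued against, since at least 12 of 17 markers were lower whichever control was left out. Members of the other lists and groups were not counted this way, though no camera call of the 6 lists against controls ended without 1 array. A smaller share of marrow and bone in the exercised dissections may account for the granulocyte and osteoclast falls, since within groups their means moved together over 12 arrays (r = 0.890). Cell cycle transcripts may come with it, since their mean moved with the granulocyte mean (r = 0.952). These r cannot tell such a share from a difference in spread between arrays, which would also move lower lists together. On the 3 arrays of 2 days the SD of the values relative to controls was 0.380, 0.493 and 0.482. The osteoclast mean was -0.80, -1.90 and -1.62 on them, and the glucocorticoid mean, which rose, was 0.49, 0.88 and 0.92. That SD measures how far an array lies from the control mean. A different share of marrow would change it too, so it cannot decide between the share and the spread. For the erythroid list that share cannot be told apart, because its r was 0.357 with osteoclasts and 0.640 with granulocytes and neither passed, and the lymphoid and osteoblast lists were not tested this way. Of the 4 relations, tested by exact permutation within groups (1296 permutations), granulocyte with osteoclast (rho = 0.881, p = 0.00154 and 0.00386 for r and rho, adjusted p = 0.00463 and 0.00772, r = 0.883 without the 2 farthest arrays) and with cell cycle (rho = 0.797, p = 0.00231 and 0.00386, adjusted p = 0.00463 and 0.00772, r = 0.927) passed, while granulocyte with erythroid (rho = 0.559, p = 0.0563 and 0.0802, adjusted p = 0.0751 and 0.107, r = 0.545) and erythroid with osteoclast (rho = 0.350, p = 0.136 and 0.214, adjusted p = 0.136 and 0.214, r = 0.170) did not. A difference in the spread of arrays left by the normalization cannot be told apart, because quantile normalization of values centred on the controls stretches the deviations of the controls by construction. After it 6 of 18 results (6 lists, 3 groups) lay below all genes by more than 3 SE, with sizes from 1.55 to 6.57 SE. All 18 were still called lower by camera at the preset correlation (highest adjusted p = 8.29e-04). They kept 64.6% to 80.2% of their difference from all genes. A difference that depends on signal level was not tested, since no level is kept, and a change in the marrow or bone itself with exercise stays open, as untested.

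The clock and glucocorticoid lists were called higher in the exercised groups, with 6, 7 and 8 of 14 members of each passing at 2, 5 and 15 days and Npas2 lower at 5 days. The lowest adjusted p with an estimated correlation was 0.325 for the clock and 0.313 for the glucocorticoid list. A larger share of chondrocyte RNA cannot be told apart, because the members of the chondrocyte lists (matrix, regulators and proteoglycan synthesis) went both ways. The glucocorticoid median exceeded theirs by at least 0.26 and the clock median by at least 0.0388, both beside the regulators at 2 days, where the SD of the members was 0.418. The regulator and proteoglycan synthesis lists were called higher at 2 and 5 days and the marrow, bone and endothelial lists lower, as that share would need. None of these calls passed with an estimated correlation. The regulator call at 2 days and the proteoglycan calls at 2 and 5 days ended without 1 array. Against a larger chondrocyte share, the cartilage matrix median was -0.14, -0.17 and -0.16 at 2, 5 and 15 days, Col2a1 fell in each group (-0.48, -0.44 and -0.84) and Matn3 too (-2.76, -3.37 and -3.34), and Acan and Hapln1 did not pass. Other matrix members rose, among them Prg4 in each group, as did the chondrocyte protein gene Cytl1 outside the list. The SD of the matrix members was 0.892, 1.06 and 1.24, far larger than these medians. A different clock phase between groups cannot be told apart from exercise: output genes minus activators differed from controls by 0.0994 (SE 0.372) at 2 days, 1.06 at 5 days and 1.26 at 15 days, and the labels give no hour of dissection. An effect of the exercise itself stays open, as untested.

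Skeletal muscle transcripts were uneven between replicates. Muscle carried over with the cartilage cannot be told apart from other sources, because the second of the 15-day arrays was singled out by its muscle mean (1.80 against -0.42 and -1.69), so that the 19 of 20 markers highest on it restate the pattern. No biological explanation was tested.

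Splits of 6 arrays into 3 and 3 number 10, too few for a share under 0.05. The real split called 2914 genes at 2 days (highest other 0), 2800 at 5 days (0), 3251 at 15 days (4), 0 from 2 to 5 days (0, so that 10 of 10 splits gave as many), 33 from 5 to 15 days (15) and 130 from 2 to 15 days (105). In the other comparisons 1 of 10 splits, the real one, gave as many. For the 4 groups 1 of 100 splits, the real one, reached 3226 genes, with 2430 as the highest other. This is the smallest share that 100 splits can give, and it lies under 0.05. A random split of the arrays is thus an unlikely source of that count, but it was not excluded.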

How the results depend on the processing

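The alternatives without the arrays richest in muscle markers, without the first arrays of 2 and 5 days, with the lowest probe set identifier and with every probe set were chosen after seeing the data. The filter on dim genes and the brightest probe set could not be run, since centred values keep no level, and signal over background was not analysed here. In the order 2, 5 and 15 days against controls, 5 against 2, 15 against 5 and 15 against 2 days, and all 4 groups, quantile normalization once more called 765, 804, 678, 0, 0, 0 and 540 genes. By its construction it stretches the controls, since the values are centred on controls, whose arrays had an SD of 0.147 to 0.183 against 0.380 to 0.552. Changes were also smaller after it between durations, where no controls are compared. From 2 to 15 days Aspn was at 1.67 against 2.21 and Col9a1 at -0.92 against -1.53. How much each contributed to the lost calls was not tested. An unadjusted p under 0.05 with a fold of 2 gave 601, 657, 655, 2, 90, 98 and 888. For the others the cause was not tested. A trended robust prior gave 117 genes from 5 to 15 days and medians subtracted gave 16. Array weights gave 3, 374 and 621 genes between durations in the order above. With only the groups compared, 1 gene passed from 5 to 15 days and 0 from 2 to 15 days. Without the muscle-rich arrays the counts were 1848 at 2 days, 1923 at 15 days, 18 from 5 to 15 days, 61 from 2 to 15 days and 1610 over all groups, and without the first arrays 246 and 309 from 5 and 2 to 15 days. The counts not given here stayed within 1.5 times.

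The replicate number as a block gave 2965, 2858, 3287, 0, 136, 203 and 3278 genes. Of 18 pairs of arrays with the same number, r of the deviations ran from -0.123 to 0.412 and 9 exceeded 0.1. Not every pair did, so the 4 groups were kept unpaired. Between 2 and 5 days all 3 pairs did (0.412, 0.245 and 0.152), where the block changed no list call. That 10 of 12 arrays correlated best with one of their own number is a hint from the data at something shared by number, which the labels do not name.

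Leaving out each array in turn gave 1535 to 3160 genes at 2 days, 1719 to 3022 at 5 days, 2237 to 3331 at 15 days, 0 to 2 from 2 to 5 days, 0 to 184 from 5 to 15 days, 0 to 301 from 2 to 15 days and 1919 to 3545 over all groups. Where 2 arrays remained in a group, they were assumed to vary like the other groups. Lists called ran over 20 to 22, 19 to 24, 15 to 21, 2 to 7, 8 to 15 and 12 to 17. With an estimated correlation 0 lists passed in each of the 6 comparisons. Against controls fry called 15 lists at 2 days, 14 at 5 days and 18 at 15 days, not all of them lists that camera called. Between durations it called 0 from 2 to 5 days and 1 each from 5 and from 2 to 15 days. From 2 to 5 days 1 list passed after quantile normalization and 5 without the first arrays. Correlations of log2 fold changes ran from 0.929 to 0.954 for 2 and 5 days, 0.784 to 0.857 for 2 and 15 days and 0.788 to 0.862 for 5 and 15 days, and were 0.975, 0.896 and 0.904 over genes past the test of all groups.

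The 537 results for named genes include those without a call. Against controls 106, 108 and 89 were called at 2, 5 and 15 days. Of these, quantile normalization ended 45, 35 and 35, and leaving out 1 array ended 22, 23 and 11. The 11 calls from 5 to 15 days and the 20 from 2 to 15 days all ended in both settings. In all, 146 results lost their call after quantile normalization, 87 when 1 array was left out, 3 with the block and 2 with array weights. In turn 24 gained one with the block and 52 with array weights. Of 91 list calls, 9 were lost after quantile normalization, 3 with the block, 35 when 1 array was left out, 12 without the muscle-rich arrays, 12 without the first arrays, 45 with fry and all 91 with an estimated correlation. Panel genes that had not passed changed sign in these cases. Leaving out 1 array, Hapln1 was -0.0569 and Col10a1 -0.23 at 2 days, Adamts5 -0.13, Timp3 -0.0161 and Nos2 0.0873 at 5 days, and Hapln1 -0.0527 and Vegfa 0.0234 at 15 days. From 2 to 5 days Col2a1 was -0.0324, Hapln1 -0.00287, Mmp3 -0.20, Mmp13 0.39, Adamts5 0.0315, Ptgs2 0.16, Ldha 0.0411, Ugdh -0.039 and Papss2 0.055. From 5 to 15 days Prg4 was -0.0415, Hapln1 0.00706, Col10a1 -0.19, Mmp13 0.60, Ptgs2 -0.0221 and Ldha 0.0521. From 2 to 15 days Acan was 0.033, Hapln1 -0.0470, Mmp13 0.44, Ptgs2 0.33, Il1b -0.0438 and Nos2 0.11. With array weights Adamts5 was -0.0104 at 5 days, Mmp13 0.0789 from 2 to 5 days, Prg4 -0.00437 from 5 to 15 days, and Acan 0.0207 and Ptgs2 0.15 from 2 to 15 days. After quantile normalization Prg4 was -0.0747, Col10a1 -0.0584, Mmp13 0.13 and Hif1a -0.018 from 5 to 15 days, and Hapln1 -0.00668 from 2 to 15 days.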

Other observations

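Genes that were chosen after their values were seen are given here as values. Of the genes called at 2 days, 28 passed in the opposite direction from 2 to 15 days and 14 in the same direction, and 88 genes passed from 2 to 15 days without a call at 2 days. Both comparisons use the same 2-day arrays with opposite sign, so noise in those arrays favours opposite calls. The counts expected with no change were not estimated, and an opposite call does not mean a return to the control level. Among the 28, the chromatin enzymes Jmjd1c and Jmjd6, the phosphodiesterase Pde3b and the hedgehog effector Gli2 were higher at 2 days. The extracellular glycoprotein reelin (Reln), the peroxiredoxin Prdx6 and the protease legumain (Lgmn) were lower at 2 days. The log2 value of the clock activator Bmal1 was -0.02, 1.38 and 1.34 on the 3 arrays of 2 days, -0.05, 0.00028 and 0.33 on those of 5 days, and -0.37, -0.78 and -0.63 on those of 15 days. Its partner Npas2 was at -1.01, 0.22 and 0.21 on the arrays of 2 days.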
